A study of Mus musculus with 12 samples.

How the data were processed

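RNA was measured in 12 libraries of HoxB8 cells, mouse bone marrow progenitors immortalised by a Hoxb8 that is active only while estrogen is in the medium. Per the labels, the cells grew in RPMI with fetal bovine serum, medium conditioned with stem cell factor and estrogen, and estrogen was taken away for 24 h before RNA was extracted with a Qiagen RNeasy Plus Micro kit. Each cell population carried a pair of vectors. The first, pMIG, was empty or held Asxl1-MT2, which the design text calls a truncation of Asxl1. The second, pMICH, was empty or held CSF3R with the T618I change, a mutation of the receptor for granulocyte colony-stimulating factor. The 4 resulting groups, written below as Empty/Empty, Empty/T618I, Asxl1-MT2/Empty and Asxl1-MT2/T618I, had 3 libraries each. Libraries were prepared by BGI, per the labels' protocols.

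The authors deposited a single table of raw counts per gene symbol with 1 column for each library. Per the submitters' processing notes, the build was mm10 and the tools were Trimmomatic, STAR and DESeq2, with no version, role or order. The counting tool, the gene annotation and the strand setting were not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical family members such as the Mcpt, Stfa, Ear, Oas, Ly6 and Ifi200 families, could therefore be split in ways that cannot be followed, and values of such genes are uncertain. It is also not given whether reads of the Asxl1 and CSF3R constructs were counted to the mouse genes Asxl1 and Csf3r.

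The deposited columns name the group and a letter from A to C, and the titles number the libraries from 1 to 3. Nothing links the letters to the numbers. The genotype label of the library titled Empty/Empty 3 reads pMIG-Empty with pMICH-CSF3R-T618I, against its title, and a library titled Empty/T618I 3 exists as well. Groups were taken from the titles. Because the letter of the library in question is not given, each Empty/Empty library was left out in turn and counted as Empty/T618I in turn. Nothing in the labels says that libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

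The table holds 24411 symbols, of which 7965 had 0 counts in every library. Total counts ran from 9341984 to 10252291 per library, and 13222 to 13953 symbols had at least 1 count. The filterByExpr function of edgeR kept 11578 symbols, which hold 99.94% of the counts. In simulated data with known changes, drawn from the real means and depths over 11432 genes, the comparison of Asxl1-MT2/T618I with Empty/T618I recovered 74.6% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold, and called 13 unchanged genes. For the interaction these shares were 38.8%, 82.1% and 100%, with 9 unchanged genes called. The changed genes were drawn among those with a mean of at least 5 CPM, so the shares do not cover genes at lower levels. For the comparisons of Empty/T618I and of Asxl1-MT2/Empty with Empty/Empty, where nothing was changed, 1 and 0 genes were called.

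Counts were scaled with TMM factors, which ran from 0.919 to 1.03 and were lowest in the 3 Asxl1-MT2/T618I libraries. A model with a mean for each of the 4 groups was fitted to all 12 libraries with the quasi-likelihood functions of edgeR 4.0.16 in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. Levels are CPM, that is, counts scaled to a common library total, given as mean ± SD of 3 libraries. Log2 fold changes are given with their standard error (SE). Where a group had 0 counts in all libraries, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts, the ratio of summed counts is given with its exact 95% interval. Such floors and intervals cover counting error only, since reads copied by PCR are not independent molecules.

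Before the data were examined, the comparisons and their tests, 26 gene lists and the rule for genes named in the text were fixed. Some tests of technical explanations were chosen later, as the closing section says. The lists cover primary, secondary and tertiary granule genes, granulocyte transcription factors, monocyte, progenitor, megakaryocyte and erythroid, mast cell and basophil, dendritic, lymphoid, and stromal genes, JAK-STAT feedback, interferon, NF-kB, proliferation, Myc and ribosome biogenesis, p53, immediate early, cholesterol, glycolysis, ATF4, heat shock, Polycomb and BAP1, Hox cluster, NADPH oxidase and phagocyte, and mitochondrially encoded genes. None of the 13 mitochondrially encoded genes was in the table, and the Hox cluster list had 3 tested members and was only counted. Lists were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way and whose mixed p asks whether they move at all. The genes named are Asxl1, Csf3r and Hoxb8, a set of genes of granulocyte development and receptor signalling, the 5 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap between the groups (except for the interaction), and for each list up to 4 members with the smallest p and up to 2 that did not pass. Ly6g, on the fixed set, was not analysed here. Some genes that met these rules are not reported.

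Symbols were matched to RefSeq genes of GRCm38.p6, which has the coordinates of mm10. Of the symbols, 23194 matched directly and 1109 through a synonym. The alternatives were DESeq2 1.42.0, median-ratio and upper-quartile scaling, no low-count filter and a stricter one, a block for the column letter, a fit of only the groups compared, a fold threshold, the label of each Empty/Empty library changed, and each library left out. Scaling by library size only, a filter at 5 CPM and a fit without the libraries of letter C were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.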

Results

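The series asked whether a truncated Asxl1 changes the differentiation of cells that carry the CSF3R mutation T618I. ASXL1 is a chromatin regulator that works with the BAP1 deubiquitinase, and CSF3R is the receptor that drives neutrophil production. RNA of HoxB8 progenitor cells was sequenced 24 h after estrogen was taken away, in 4 groups of 3 libraries (Empty/Empty, Empty/T618I, Asxl1-MT2/Empty and Asxl1-MT2/T618I). Library totals lay between 9341984 and 10252291 counts. Mpo, which encodes the peroxidase of primary granules, was the gene with the most counts in all 12 libraries, at 3.35% of the counts in Empty/Empty library A and 0.839% in Asxl1-MT2/T618I library A.

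The 4 groups separated on the first 2 principal components, which held 69.9% and 16.6% of the variance of the log2 CPM values. The T618I groups lay apart from the groups without it on PC1, and Asxl1-MT2/T618I lay apart from Empty/T618I on PC2. The libraries of a group differed by more than counting noise, so none was treated as a copy of another. PC4, with 2.36% of the variance, held the letter C libraries of Empty/Empty, Empty/T618I and Asxl1-MT2/Empty at 16.3, 15.2 and 11.2, above the other libraries of those groups.

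**Figure D1:**
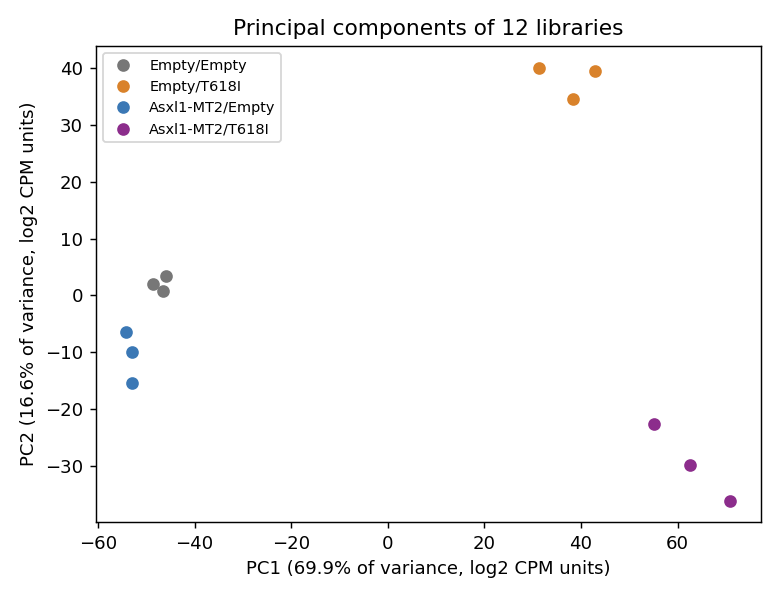
Principal components of log2 CPM values, with PC1 (69.9% of the variance) on the horizontal and PC2 (16.6%) on the vertical axis and 1 point for each of the 12 libraries, coloured by group. The Asxl1-MT2/T618I libraries lie between 55.2 and 70.9 on PC1 and the Asxl1-MT2/Empty libraries between -54.2 and -53.0.

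The construct genes were examined first, as a check of the labels. Asxl1 (chromosome 2, 153345830 to 153404007, GRCm38.p6) was at 119 ± 4.52 CPM in Empty/Empty and 148 ± 16.9 in Empty/T618I, against 1743 ± 79.8 in Asxl1-MT2/Empty and 1004 ± 83.6 in Asxl1-MT2/T618I (SD, n = 3). The 6 libraries labelled Asxl1-MT2 all lay above the 6 without it. Csf3r (chromosome 4, 126023441 to 126044975) was at 298 ± 57.5 CPM in Empty/Empty, 431 ± 39.3 in Empty/T618I, 293 ± 35.5 in Asxl1-MT2/Empty and 1329 ± 360 in Asxl1-MT2/T618I. Its rise with T618I alone was small (log2 fold change 0.53 ± 0.167, SE; edgeR quasi-likelihood adjusted p = 0.0198) and did not pass without Empty/Empty library C (adjusted p = 0.0746 in the same edgeR test). Since the table does not show whether construct reads count to the mouse gene, Csf3r alone does not check the T618I labels. Socs3, the feedback inhibitor that CSF3R signalling induces, was at 12.7 ± 0.972 CPM in Empty/Empty and 10.7 ± 0.361 in Asxl1-MT2/Empty, against 165 ± 12.6 in Empty/T618I and 229 ± 34.0 in Asxl1-MT2/T618I. In the library titled Empty/Empty 3, whose genotype label names T618I, the column letter is not known, but Socs3 was at 13.8, 11.9 and 12.4 CPM in the Empty/Empty libraries A, B and C. Hoxb8 (chromosome 11, 96279401 to 96285325) was at 660 ± 40 CPM in Empty/Empty, 291 ± 45.4 in Empty/T618I, 720 ± 65.0 in Asxl1-MT2/Empty and 571 ± 13.5 in Asxl1-MT2/T618I. Asxl1 was lower in Asxl1-MT2/T618I than in Asxl1-MT2/Empty, with a log2 fold change of -0.80 ± 0.0882 (edgeR quasi-likelihood adjusted p = 9.55e-07).

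**Figure D2:**
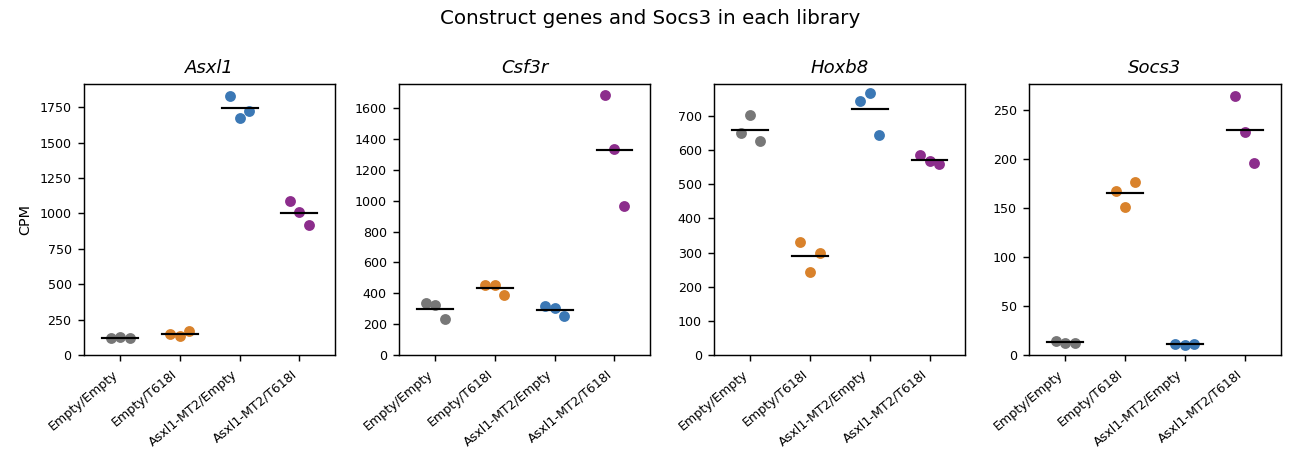
Levels of Asxl1, Csf3r, Hoxb8 and Socs3 in CPM on linear axes that start at 0, with 1 point for each library and a line at the mean of each group of 3. Asxl1 averages 1743 and 1004 CPM in the groups with Asxl1-MT2 against 119 and 148 in those without, and Socs3 averages 165 and 229 CPM in the groups with T618I against 12.7 and 10.7.

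To describe T618I on its own, Empty/T618I was compared with Empty/Empty. Among the genes that changed were several of neutrophil maturation. Mmp8, the collagenase of secondary granules, went from 6.17 ± 2.00 to 201 ± 25.0 CPM. Cxcr2, the chemokine receptor of circulating neutrophils, went from 24.1 ± 3.89 to 193 ± 29.6 CPM, and both were higher in 3 of 3 libraries. Mpo fell from 29710 ± 4350 to 11990 ± 944 CPM, and Kit, the receptor for stem cell factor, from 326 ± 24.4 to 105 ± 6.88 CPM. Hoxb8 counts were lower too, as given above, and whether this had a part in these changes was not tested. Socs3 was 1 of the genes with the smallest p, at a log2 fold change of 3.70 ± 0.118 (edgeR quasi-likelihood adjusted p = 9.57e-13). In total 2038 genes rose and 1840 fell out of 11578 tested, with an absolute log2 fold change of at least 1 for 1345 of them. No Empty/Empty library had a Socs3 level or a PC1 position near those of Empty/T618I, with PC1 between -48.5 and -46.0 against 31.4 to 43.0. With Empty/Empty library A, B or C nonetheless counted as Empty/T618I, as the disputed label would have it, edgeR called 0, 0 and 995 genes (2646, 2506 and 3593 at an unadjusted p under 0.05). DESeq2 called 973, 726 and 1874. Such a label mixes unlike libraries in a group and so puts the T618I difference into the spread. The fall in calls is therefore no measure of how firmly the calls hold.

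Of 34 tested genes of tertiary granules and mature neutrophils, 28 rose and 3 fell (29 and 4 when adjusted over the list alone), with a median log2 fold change of 1.36 (camera adjusted p = 1.48e-11, and adjusted p = 0.335 with an estimated correlation). Mmp9, the gelatinase, rose by 3.96 ± 0.288 on the log2 scale, Il1r2, the decoy receptor for interleukin 1, by 2.93 ± 0.148, and S100a9, a subunit of calprotectin, by 1.70 ± 0.190. Itgam, the integrin chain CD11b, did not pass (188 ± 28.2 against 226 ± 18.2 CPM). The secondary granule list was split, with 10 of 22 genes higher and 6 lower (11 and 7 when adjusted over the list alone; camera adjusted p = 0.103). Its fry adjusted p was 0.0277 for movement in one direction and 3.45e-07 for movement in any direction. Lcn2, which binds bacterial siderophores, rose by 1.46 ± 0.139. Camp, the cathelicidin peptide, fell by 2.03 ± 0.314, and Fcnb, a ficolin, fell by 4.13 ± 0.284. Ltf, which encodes lactoferrin, was at 97.6 ± 26.4 CPM against 91.7 ± 44.0 and Ngp at 392 ± 101 against 595 ± 211, and neither passed. Of 15 primary granule genes, 1 rose and 11 fell (2 and 11 when adjusted over the list alone; camera adjusted p = 1.64e-05, and adjusted p = 0.159 with an estimated correlation). Ctsg fell by 0.83 ± 0.0985 and Prtn3 fell by 0.67 ± 0.110 on the log2 scale. Elane fell by 0.41 ± 0.130 (edgeR quasi-likelihood adjusted p = 0.0212), which did not pass when any of 5 libraries, the 3 Empty/Empty libraries and Empty/T618I libraries A and C, was left out (adjusted p up to 0.143 in edgeR). Of 13 granulocyte transcription factors, 6 rose and 3 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.626). Rara, a retinoic acid receptor, rose by 3.27 ± 0.234. Gfi1 and Cebpe, regulators of neutrophil maturation, fell by 1.06 ± 0.109 and 0.87 ± 0.111. Of 24 NADPH oxidase and phagocyte receptor genes 15 rose and 1 fell (17 and 1 when adjusted over the list alone; camera adjusted p = 1.28e-05, and adjusted p = 0.389 with an estimated correlation). Cybb, the catalytic subunit of the oxidase, was at 74.1 ± 7.62 against 23.3 ± 3.35 CPM.

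Genes induced by cytokine receptor signalling rose together. Of 22 such genes 18 rose and 1 fell, the same numbers when adjusted over the list alone, and this was the list whose call held with an estimated correlation (camera adjusted p = 7.88e-12, and adjusted p = 0.0335 with an estimated correlation). Il4ra rose by 3.21 ± 0.110 on the log2 scale, the cytokine gene Osm by 2.92 ± 0.136, and Cish, a further feedback inhibitor, by 2.33 ± 0.139. Of 20 NF-kB targets, cytokines and chemokines 16 rose and 0 fell (18 and 0 when adjusted over the list alone; camera adjusted p = 1.1e-07, and adjusted p = 0.304 with an estimated correlation). Il6 (14.6 ± 6.23 against 0.943 ± 0.121 CPM) and Ccl3 were among them. Of 26 immediate early genes 15 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.000231, and adjusted p = 0.304 with an estimated correlation). Egr1 was higher by 4.15 ± 0.277 and Junb by 1.83 ± 0.109. Of 19 p53 targets 13 rose and 1 fell (14 and 1 when adjusted over the list alone; camera adjusted p = 4.06e-05, and adjusted p = 0.159 with an estimated correlation). The cell cycle inhibitor Cdkn1a was at 98.0 ± 4.63 against 29.4 ± 5.90 CPM. Of 11 heat shock genes 8 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.335 with an estimated correlation). Of 25 Myc and ribosome biogenesis genes 9 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00796, and adjusted p = 0.641 with an estimated correlation). Myc itself was at 351 ± 52.0 against 382 ± 37.4 CPM, which did not pass. Interferon response genes (9 of 27 higher, 3 lower), S and G2/M phase genes (10 of 37 higher, 2 lower), cholesterol synthesis genes (1 of 21 higher, 5 lower), glycolysis genes (8 of 27 higher, 5 lower) and Polycomb and BAP1 genes (3 of 25 higher, 4 lower) had camera adjusted p-values of 0.181, 0.105, 0.626, 0.611 and 0.626. When adjusted over the list alone, those counts were 9 and 3, 10 and 2, 1 and 5, 9 and 6, and 3 and 3. The Polycomb list had a median of 0.01 and a mean of -0.08, with a camera direction of down. Of 25 ATF4 and unfolded protein response genes 10 rose and 8 fell (11 and 9 when adjusted over the list alone; camera adjusted p = 0.626). The amino acid transporter gene Slc7a5 was higher by 1.67 ± 0.0898. Herpud1, a gene of protein degradation at the endoplasmic reticulum, had a log2 fold change of -0.85 ± 0.0705. Hoxb4 was the 1 gene of 3 tested Hox cluster genes that rose (1 and 0 when adjusted over the list alone).

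Genes of mast cells and basophils were among the largest increases. Mcpt8, a basophil protease gene, went from 94.0 ± 12.6 to 1111 ± 314 CPM. Il1rl1, the receptor for interleukin 33, went from 9.39 ± 2.35 to 333 ± 129 CPM, and Mcpt1 from 0.135 ± 0.0578 to 1063 ± 448 CPM. Fcer1a, a chain of the IgE receptor, had 0 counts in Empty/Empty and was at 23.7 ± 12.7 CPM in Empty/T618I, at least 235-fold higher. Of 17 genes in the list 12 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 1.64e-05, and adjusted p = 0.389 with an estimated correlation). The eosinophil granule genes Prg2 and Prg3 did not pass. Of 11 megakaryocyte and erythroid genes 8 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.00358, and adjusted p = 0.36 with an estimated correlation). Gata1, the erythroid and mast cell transcription factor, went from 4.95 ± 0.422 to 47.4 ± 12.9 CPM, and Gata2, which acts in stem cells and mast cells, from 66.3 ± 5.09 to 408 ± 99.7 CPM. The 21 stem and progenitor genes were split at 6 higher and 7 lower, also when adjusted over the list alone, with a median of -0.19 and a mean of 0.28 on the log2 scale (camera adjusted p = 0.671). Of 21 monocyte and macrophage genes 10 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.607 with an estimated correlation). Of the lymphoid genes 3 of 7 rose and 3 fell, of the dendritic genes 2 of 7 rose and 3 fell, and of the stromal genes 1 of 5 rose and 0 fell (3 and 3, 4 and 3, and 1 and 0 when adjusted over the list alone), with camera adjusted p-values of 0.626, 0.901 and 0.626. Medians and means of these 3 lists differed in sign, at -0.54 and 1.23, 0.33 and -0.04, and -0.05 and 0.20, with camera directions down, down and up. The lymphoid receptor gene Il7r had 1 count in Empty/Empty and 2093 in Empty/T618I, a ratio of 2040 (95% counting interval 366 to 80600). Alox8 had 0 counts in Empty/Empty and was at least 503-fold higher. Igll1, a gene of the pre-B-cell receptor, fell by 5.47 ± 0.351 on the log2 scale, the largest fall, followed by Afap1, Dlg2, Ednra and Mgl2.

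**Figure D3:**
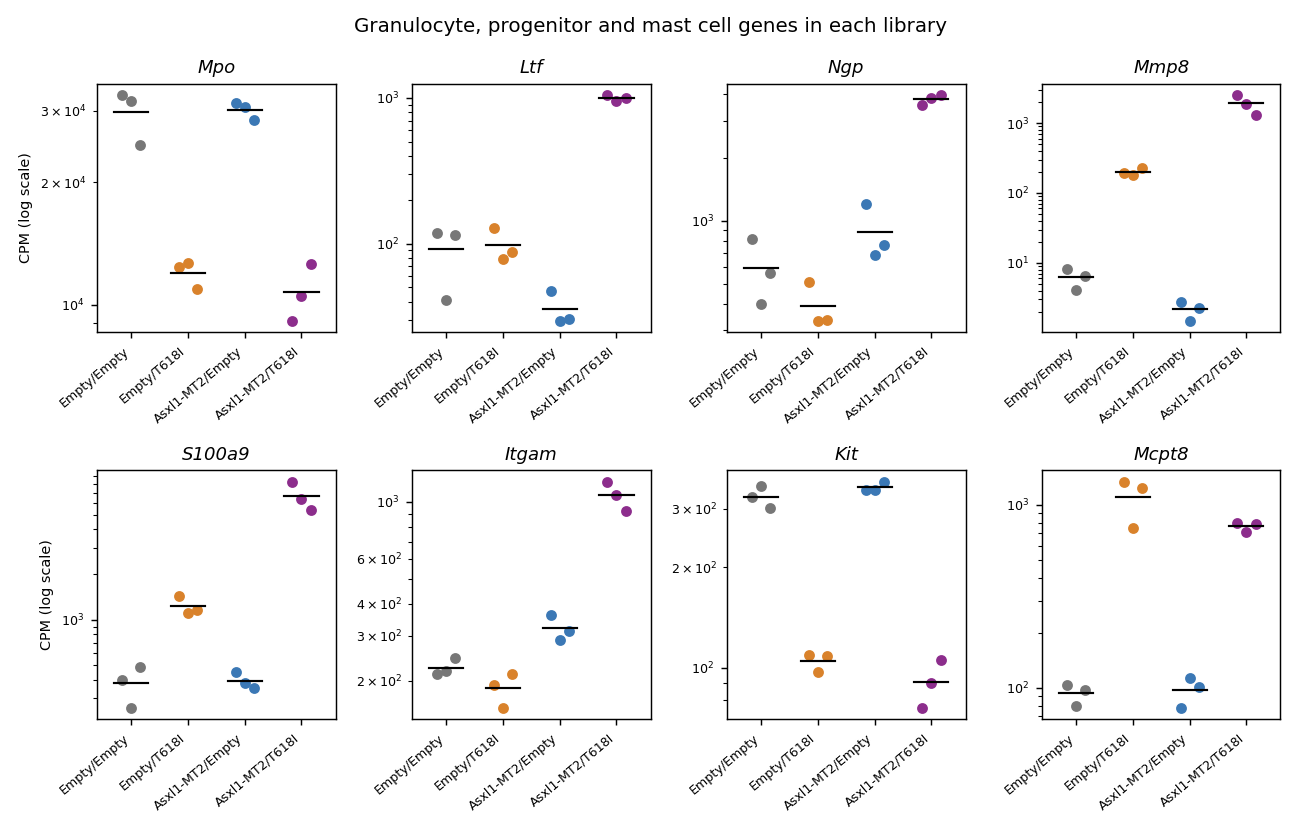
Levels of Mpo, Ltf, Ngp, Mmp8, S100a9, Itgam, Kit and Mcpt8 in CPM on log axes, with 1 point for each library and a line at the mean of each group of 3. Ltf averages 1001 CPM in Asxl1-MT2/T618I and 35.7 to 97.6 CPM in the other groups, and Mpo averages 10730 and 11990 CPM in the groups with T618I against 29710 and 30180 in those without.

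The effect of truncated Asxl1 alone was read from Asxl1-MT2/Empty against Empty/Empty. Few genes changed, among them single mast cell and progenitor genes that fell. Cd34, a surface marker of progenitors, went from 222 ± 17.5 to 113 ± 21.3 CPM, and Cpa3, a mast cell carboxypeptidase gene, from 571 ± 51.3 to 269 ± 27.4 CPM, each lower in 3 of 3 libraries. Apart from Asxl1 itself, higher by 3.87 ± 0.0994 on the log2 scale, the largest increases were those of Dlk1, an imprinted regulator of differentiation (1.12 ± 0.426 to 13.7 ± 4.14 CPM), Mgll, a monoacylglycerol lipase gene (5.89 ± 0.660 to 22.3 ± 2.85 CPM), Tmem108 and Nt5e. The largest falls were those of Lpxn, which fell by 2.19 ± 0.277, Prg2, which fell by 2.16 ± 0.354, Tulp3, Il1rl1 and Fyb. The call of Il1rl1 (edgeR quasi-likelihood adjusted p = 0.0346) was lost without any 1 of 5 libraries, Empty/Empty A and C and the 3 of Asxl1-MT2/Empty (edgeR adjusted p up to 0.188). The edgeR quasi-likelihood test called 143 genes higher and 72 lower, of which 81 had an absolute log2 fold change of at least 1. The count of 215 fell to 60 without Asxl1-MT2/Empty library A, to 106 without its library B, and to 101, 104 and 136 without Empty/Empty libraries A, B and C. It was 386 without the letter C libraries and 359 with no low-count filter. With Empty/Empty library A, B or C counted as Empty/T618I it was 5, 4 and 6. No Empty/Empty library resembled Empty/T618I, so that label puts the T618I difference into the spread shared by all groups. These 3 counts therefore say little about the 215 calls.

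Of the mast cell, basophil and eosinophil list 0 rose and 7 of 17 fell (0 and 10 when adjusted over the list alone; camera adjusted p = 1.15e-08, and adjusted p = 0.351 with an estimated correlation). Of the progenitor list 0 of 21 rose and 4 fell, Cd34, Angpt1, Gata2 and Hoxa9 (0 and 5 when adjusted over the list alone; camera adjusted p = 9.52e-06, and adjusted p = 0.322 with an estimated correlation). Hoxa9, a leukaemia-associated homeobox gene at 0.198 ± 0.171 against 1.72 ± 0.115 CPM, was 1 of 3 tested Hox cluster genes and the 1 that fell, at an edgeR quasi-likelihood adjusted p of 0.0472 that was lost without any 1 of 7 libraries, the 6 of this comparison and Asxl1-MT2/T618I B (adjusted p up to 0.201 in edgeR). Of 11 megakaryocyte and erythroid genes 0 rose and 1 fell, Gata1 (0 and 6 when adjusted over the list alone; camera adjusted p = 2.06e-05, and adjusted p = 0.308 with an estimated correlation). The calls of Gata1 and Gata2 were lost without Empty/Empty library A or Asxl1-MT2/Empty library A or B (edgeR adjusted p up to 0.0901 and 0.0865). By the directional fry test the mast cell, progenitor and megakaryocyte lists did not pass (fry adjusted p = 0.303, 0.134 and 0.134). Nor did the primary granule list (fry adjusted p = 0.0703). Of 15 primary granule genes 3 rose and 0 fell (6 and 0 when adjusted over the list alone; camera adjusted p = 4.52e-06, and adjusted p = 0.293 with an estimated correlation). These were Clec12a, Nkg7 and Elane, higher by 0.43 ± 0.0940, 0.56 ± 0.124 and 0.55 ± 0.130, and each call was lost without Empty/Empty library B or Asxl1-MT2/Empty library A or B. Clec12a was also lost without Empty/Empty A, Nkg7 without Empty/Empty C, and Elane without any of 5 others, Empty/Empty A and C, Empty/T618I A, Asxl1-MT2/Empty C and Asxl1-MT2/T618I B (edgeR adjusted p up to 0.149, 0.138 and 0.19). Of the mature neutrophil list 6 of 34 rose and 1 fell (12 and 7 when adjusted over the list alone; camera adjusted p = 0.109), with a median of 0.03 and a mean of -0.36 on the log2 scale. With 1 library left out, over the same genes, that median ran from -0.0679 (without Asxl1-MT2/Empty A) to 0.15 (without Asxl1-MT2/Empty C), so its sign is not settled. BC100530, a member of the stefin A family whose copies share reads, rose by 1.03 ± 0.161. Of the secondary granule list 2 of 22 rose and 1 fell (5 and 5 when adjusted over the list alone; camera adjusted p = 0.185), with a median of 0.15 and a mean of -0.21. With 1 library left out, over the same genes, the secondary granule median ran from 0.0601 (without Asxl1-MT2/Empty A) to 0.187 (without Asxl1-MT2/Empty B). The list had 1 higher and 2 lower when scaled by library size only. The gene that fell was Ltf, at 35.7 ± 10.2 against 91.7 ± 44.0 CPM (edgeR quasi-likelihood adjusted p = 0.0233, and up to 0.136 in edgeR when 1 of 4 libraries, Empty/Empty A and C and Asxl1-MT2/Empty B and C, was left out).

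Of 24 NADPH oxidase and phagocyte genes 2 rose and 0 fell (6 and 2 when adjusted over the list alone; camera adjusted p = 0.00215, and adjusted p = 0.576 with an estimated correlation), and Itgam was among them. The call of Itgam was lost without Empty/Empty library A or B, Asxl1-MT2/Empty library A or C or Asxl1-MT2/T618I library B (edgeR adjusted p up to 0.214). The list had a median of 0.15 and a mean of -0.01 on the log2 scale. No gene of the JAK-STAT, NF-kB, proliferation, cholesterol, ATF4, heat shock, lymphoid or stromal lists, nor of the granulocyte transcription factor or ribosome biogenesis lists, was called by edgeR. Adjusted over the list alone, 1 transcription factor rose and 1 fell, 1 lymphoid gene rose, 2 stromal genes rose and 2 fell, 1 ribosome biogenesis gene fell, and 0 genes of the other 6 lists were called. Camera placed the ribosome biogenesis genes lower (median log2 fold change -0.15, adjusted p = 5.89e-07, and adjusted p = 0.398 with an estimated correlation) and the cholesterol genes higher (median 0.14, camera adjusted p = 1.29e-06, and adjusted p = 0.293 with an estimated correlation). By the directional fry test the ribosome biogenesis, cholesterol and NADPH oxidase lists did not pass (fry adjusted p = 0.247, 0.0667 and 0.468). The monocyte list had 2 of 21 genes higher and 1 lower, the glycolysis list 2 of 27 higher and 0 lower, the interferon list 1 of 27 higher and 0 lower, and the p53, immediate early and dendritic lists 1 gene lower each and 0 higher. When adjusted over the list alone these counts were 2 and 3, 3 and 0, 1 and 0, 0 and 1, 1 and 2, and 0 and 1. Asxl1 was the 1 called gene of 25 in the Polycomb and BAP1 list (1 when adjusted over the list alone). Signs differed within the dendritic list (median -0.12, mean 0.32, camera down), the stromal list (0.07, -0.37, up), the Polycomb list (-0.02, 0.15, up) and the interferon list (0.02, 0.03, down). Csf3r (293 ± 35.5 against 298 ± 57.5 CPM), Hoxb8, Mpo and Socs3 did not pass.

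To ask what truncated Asxl1 did in cells with the CSF3R mutation, Asxl1-MT2/T618I was compared with Empty/T618I. Single genes of neutrophil granules and of mature neutrophils rose. Ltf went from 97.6 ± 26.4 to 1001 ± 50.2 CPM, Ngp, the neutrophilic granule protein gene, from 392 ± 101 to 3796 ± 220 CPM, and S100a9 from 1240 ± 178 to 6644 ± 1480 CPM, each higher in 3 of 3 libraries. Itgam, whose product CD11b marks maturing neutrophils and monocytes, went from 188 ± 28.2 to 1063 ± 137 CPM (log2 fold change 2.50 ± 0.124, edgeR quasi-likelihood adjusted p = 9.29e-10). Myc fell from 351 ± 52.0 to 193 ± 23.9 CPM and Cd34 from 215 ± 25.3 to 122 ± 25.2 CPM. In total 2939 genes rose and 2143 fell, and of the 1156 with an absolute log2 fold change of at least 1, 982 rose and 174 fell. The split depends on the scaling. It was 2326 higher and 3355 lower with upper-quartile factors and 2266 and 3514 with library size only. These moved the median log2 fold change of all genes from 0.01 to -0.10 and -0.12.

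All 34 tested mature neutrophil genes rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 2.38 (camera adjusted p = 3e-24, and adjusted p = 0.138 with an estimated correlation). The median was 2.27 and 2.25, and 33 genes rose, with upper-quartile and library size scaling. Mmp9 rose by 3.51 ± 0.218 on the log2 scale, Itgb2l, an integrin gene of neutrophils, by 2.74 ± 0.140, Mxd1 by 1.96 ± 0.107 and Cxcr2 by 1.86 ± 0.156. All 22 secondary granule genes rose and 0 fell, also when adjusted over the list alone, with a median of 2.32 (camera adjusted p = 6.64e-17, and adjusted p = 0.138 with an estimated correlation). Camp, Chil3, a chitinase-like protein gene, and Cybb rose by 2.78 ± 0.304, 2.92 ± 0.192 and 2.29 ± 0.125. Of 24 NADPH oxidase and phagocyte genes 21 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 1.45e-13, and adjusted p = 0.138 with an estimated correlation). C5ar1, the receptor for complement C5a, was at 122 ± 23.3 against 16.1 ± 3.30 CPM. Of 13 granulocyte transcription factors 7 rose and 2 fell (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0118, and adjusted p = 0.138 with an estimated correlation). Cebpe rose by 1.03 ± 0.111, Spi1 by 0.61 ± 0.0909 and Rara by 1.99 ± 0.160. Cebpa fell by 0.27 ± 0.0977 (edgeR quasi-likelihood adjusted p = 0.0335), a call lost without Empty/T618I library A or B or Asxl1-MT2/T618I library A (adjusted p up to 0.136 in edgeR). Of 15 primary granule genes 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.569), and the median log2 fold change of 0.02 was -0.09 with upper-quartile factors and -0.11 with library size only. Mpo, Elane, Prtn3 and Ctsg did not pass, with log2 fold changes of -0.16 ± 0.119, 0.11 ± 0.130, -0.11 ± 0.109 and -0.10 ± 0.0980.

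Of 21 monocyte and macrophage genes 15 rose and 0 fell (15 and 1 when adjusted over the list alone; camera adjusted p = 7.26e-07, and adjusted p = 0.138 with an estimated correlation), with 1 lower as well under library size or upper-quartile scaling. Csf1r, the receptor for macrophage colony-stimulating factor, went from 15.5 ± 4.32 to 87.3 ± 20.9 CPM, and Irf8, a monocyte transcription factor, from 0.916 ± 0.116 to 5.36 ± 1.29 CPM. Of 27 interferon response genes 18 rose and 1 fell (19 and 2 when adjusted over the list alone; camera adjusted p = 0.000202, and adjusted p = 0.138 with an estimated correlation). Oas3 and Oas2, of a family whose members share sequence, had the smallest p-values. Of 20 NF-kB targets 12 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00127, and adjusted p = 0.42 with an estimated correlation). The inhibitor gene Nfkbia was higher by 1.68 ± 0.117. Of 26 immediate early genes 14 rose and 7 fell (14 and 8 when adjusted over the list alone; camera adjusted p = 0.0302, and adjusted p = 0.42 with an estimated correlation). Klf2, a transcription factor of quiescence, was at 105 ± 20.7 against 15.0 ± 2.76 CPM. Of 22 JAK-STAT genes 12 rose and 5 fell (12 and 6 when adjusted over the list alone; camera adjusted p = 0.246). The directional fry test placed the JAK-STAT list higher (fry adjusted p = 0.00153). Bcl6 and Socs3 rose by 2.01 ± 0.156 and 0.48 ± 0.0962, and Pim1 did not pass. Of 27 glycolysis genes 12 rose and 3 fell, of 19 p53 targets 7 rose and 2 fell, and of 21 cholesterol genes 8 rose and 4 fell, the same numbers when adjusted over the list alone, with camera adjusted p-values of 0.0579, 0.476 and 0.748. With library size only, the p53 list had 5 higher and 6 lower, and the cholesterol median of 0.06 became -0.07. Of 25 Polycomb and BAP1 genes 7 rose, Asxl1 included, and 4 fell (7 and 5 when adjusted over the list alone; camera adjusted p = 0.755), and 7 rose and 8 fell with upper-quartile factors.

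All 25 Myc and ribosome biogenesis genes fell, also when adjusted over the list alone, with a median of -0.63 (camera adjusted p = 1.21e-14, and adjusted p = 0.138 with an estimated correlation). Gnl3, the nucleolar gene of nucleostemin, fell by 0.86 ± 0.0948, and Mybbp1a by 0.68 ± 0.0855. Of 21 progenitor genes 1 rose and 14 fell, also when adjusted over the list alone (camera adjusted p = 1.97e-05, and adjusted p = 0.164 with an estimated correlation). Kit, at 90.4 ± 14.9 against 105 ± 6.88 CPM, did not pass. The gene that rose was Hoxa9, at 4.40 ± 2.93 against 1.13 ± 0.546 CPM. Of 11 megakaryocyte and erythroid genes 0 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.000793, and adjusted p = 0.206 with an estimated correlation). Of 11 heat shock genes 0 rose and 8 fell (0 and 9 when adjusted over the list alone; camera adjusted p = 0.000167, and adjusted p = 0.138 with an estimated correlation). Among 25 ATF4 and unfolded protein response genes 4 rose and 12 fell (5 and 13 when adjusted over the list alone; camera adjusted p = 0.0184, and adjusted p = 0.302 with an estimated correlation). Of 37 proliferation genes 0 rose and 4 fell (0 and 1 when adjusted over the list alone; camera adjusted p = 0.0674), and 16 and 18 fell with upper-quartile and library size scaling. Of the mast cell and basophil list 1 of 17 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.0516), with Il1rl1 at 152 ± 19.5 against 333 ± 129 CPM. The dendritic, lymphoid and stromal lists had 3 higher and 2 lower, 1 and 2, and 2 and 1 (3 and 2, 2 and 2, and 2 and 1 when adjusted over the list alone), with camera adjusted p-values of 0.979, 0.726 and 0.765. The dendritic median and mean were -0.32 and 0.56 and the lymphoid ones 0.38 and 0.10, with a camera direction of down for both. The largest increases were those of Olfm1, by 4.63 ± 0.259, Mgll, Ednra, Col5a1 and Kcnn3. The largest falls were those of the tight junction gene Tjp1, which fell by 6.35 ± 0.408, Scd1, a fatty acid desaturase gene, which fell by 2.05 ± 0.291, Abca4, Itga7 and Padi3.

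**Figure D4:**
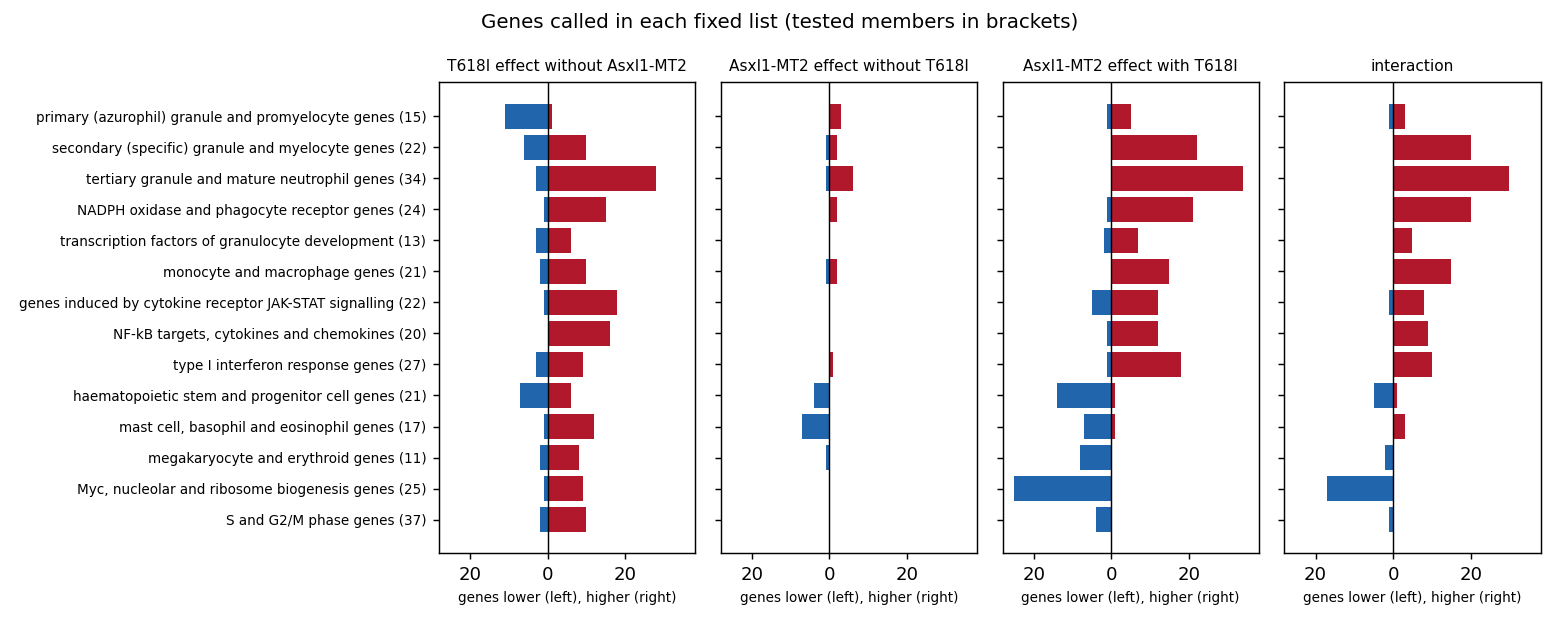
Number of genes called higher (red, right of 0) or lower (blue, left of 0) in 14 of the fixed gene lists, with the number of tested members in brackets, for 3 comparisons and for the interaction, with TMM scaling. In the comparison of Asxl1-MT2/T618I with Empty/T618I, 34 of 34 mature neutrophil genes are higher and 25 of 25 ribosome biogenesis genes are lower, and the 4 lower proliferation genes become 18 when scaled by library size only.

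Whether the effect of truncated Asxl1 differed between the backgrounds was tested with the interaction term, the log2 fold change of Asxl1-MT2 with T618I minus that without. Neutrophil genes were among those with positive values. Chil3, Mmp8 and Ltf had interaction values of 3.72 ± 0.289, 4.75 ± 0.419 and 4.72 ± 0.410, so that Ltf was lower with Asxl1-MT2 alone and higher with Asxl1-MT2 beside T618I. The largest positive values were those of Fpr1, Ceacam10, Saa3, Fpr2 and Mmp9, which include the formyl peptide receptors that sense bacteria. Fpr1 had 0 counts in Asxl1-MT2/Empty, so its fitted value of 7.88 ± 1.53 depends on the prior count. The largest negative values were those of Col18a1, Scd1, Lgr4, Top1mt and Rhoj. The edgeR call of Top1mt was lost without Empty/Empty B or Asxl1-MT2/Empty C (adjusted p up to 0.0597), and that of Rhoj without any 1 of 6 libraries, Empty/Empty A and C, the 3 of Asxl1-MT2/Empty and Asxl1-MT2/T618I B (up to 0.0903). The edgeR quasi-likelihood test called 1635 genes positive and 638 negative. Of these, 1598 of the positive ones were also higher with Asxl1-MT2 in the T618I background, and 583 of the negative ones lower. Among all 11578 genes 2939 were higher and 2143 lower in that background. The interaction contains that effect, and few genes were called for Asxl1-MT2 alone, so the agreement is largely built in. The split of the interaction calls was 1309 and 1446 with upper-quartile factors and 1312 and 1393 with library size only. With Empty/Empty library A, B or C counted as Empty/T618I the total was 711, 636 and 1488 against 2273. That label also puts the T618I difference into the spread, so fewer calls would follow in any case.

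Of the mature neutrophil list 30 of 34 genes were positive and 0 negative (32 and 0 when adjusted over the list alone), with a median of 2.15 (camera adjusted p = 5.88e-22, and adjusted p = 0.143 with an estimated correlation). Of the secondary granule list 20 of 22 were positive and 0 negative, also when adjusted over the list alone, with a median of 2.09 (camera adjusted p = 4.28e-18, and adjusted p = 0.143 with an estimated correlation). The NADPH oxidase list had 20 of 24 positive and 0 negative (20 and 0 when adjusted over the list alone; camera adjusted p = 1.87e-15), and the monocyte list 15 of 21 and 0 (16 and 0 when adjusted over the list alone; camera adjusted p = 2.57e-08), each with adjusted p = 0.143 with an estimated correlation. The ribosome biogenesis list had 0 positive and 17 of 25 negative (0 and 22 when adjusted over the list alone; camera adjusted p = 1.36e-12, and adjusted p = 0.181 with an estimated correlation). The heat shock list had 0 and 5 of 11 (0 and 7 when adjusted over the list alone; camera adjusted p = 0.000343, and adjusted p = 0.143 with an estimated correlation). Primary granule genes showed 3 positive and 1 negative value of 15, also when adjusted over the list alone (camera adjusted p = 0.355), and 1 positive and 4 negative with upper-quartile factors or library size only. The interaction of Csf3r was 1.65 ± 0.236 and that of Hoxb8 0.85 ± 0.143. Among transcription factors 5 of 13 were positive and 0 negative (6 and 1 when adjusted over the list alone; camera adjusted p = 0.106), with Cebpe at 0.84 ± 0.155.

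The effect of T618I in cells with truncated Asxl1 was taken from Asxl1-MT2/T618I against Asxl1-MT2/Empty. Mmp8 went from 2.18 ± 0.651 to 1918 ± 606 CPM, Lcn2 from 347 ± 60.9 to 3458 ± 512 CPM and Mpo from 30180 ± 1560 to 10730 ± 1750 CPM, each apart in 3 of 3 libraries. Fpr1, Spint1, Cd38, Kcnn3 and Mcpt4 had 0 counts in Asxl1-MT2/Empty and were at least 906, 505, 442, 319 and 316-fold higher. The largest falls were those of Igll1, Ptgds, Matk, Serpinf1 and Myo18b. Igll1 fell by 4.59 ± 0.351 and Ptgds, a prostaglandin synthase gene, fell by 3.61 ± 0.479 on the log2 scale. The mature neutrophil list had 31 of 34 genes higher and 1 lower (31 and 1 when adjusted over the list alone; camera adjusted p = 2.61e-20, and adjusted p = 0.102 with an estimated correlation). The mast cell and basophil list had 16 of 17 higher and 0 lower (16 and 0 when adjusted over the list alone; camera adjusted p = 1.85e-06, and adjusted p = 0.264 with an estimated correlation). The JAK-STAT list had 18 of 22 higher and 2 lower (18 and 2 when adjusted over the list alone; camera adjusted p = 2.77e-09, and adjusted p = 0.0879 with an estimated correlation). The primary granule list had 2 of 15 higher and 12 lower (2 and 13 when adjusted over the list alone; camera adjusted p = 9.69e-06, and adjusted p = 0.102 with an estimated correlation). The 3 tested Hox cluster genes, Hoxa9, Hoxb3 and Hoxb4, all rose (3 when adjusted over the list alone). By the edgeR quasi-likelihood test 3118 genes rose and 2643 fell, or 2507 and 4118 with upper-quartile factors and 2585 and 3805 with library size only, with median shifts to -0.14 and -0.12.

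With both constructs against neither, Asxl1-MT2/T618I against Empty/Empty, Nos2, the inducible nitric oxide synthase gene, had 1 count in Empty/Empty and 5391 in Asxl1-MT2/T618I, a ratio of 5580 (95% counting interval 1000 to 220000). Mcpt1 rose by 12.41 ± 0.509 on the log2 scale, and Spint1, Cd38 and Alox8, at 0 counts in Empty/Empty, were at least 495, 433 and 210-fold higher. Igll1, Matk, Serpinf1, Epha7 and Dlg2 had the largest falls. Of the mature neutrophil list 33 of 34 genes rose and 0 fell, and of the secondary granule list 21 of 22 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 1.2e-22 and 3.54e-12, and adjusted p = 0.143 for both with an estimated correlation). Gfi1, Ctsg and Prtn3 fell by 0.99 ± 0.109, 0.93 ± 0.0987 and 0.78 ± 0.110, while Cebpe was at 267 ± 18.5 against 239 ± 13.6 CPM and did not pass. By the edgeR quasi-likelihood test 3186 genes rose and 2674 fell, or 2569 and 4180 with upper-quartile factors and 2594 and 4051 with library size only, with median shifts to -0.15 and -0.14.

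The effects were then compared across genes, which are not independent replicates. T618I alone and Asxl1-MT2 alone, which share the Empty/Empty libraries, had a Pearson r of -0.16 across 11578 genes, where unchanged groups simulated against shared controls gave 0.51, and a covariance of -0.0702 against a simulated 0.02. Of their calls 48 were higher in both (25.2 for independent lists), 7 lower in both (11.4), 44 higher with T618I and lower with Asxl1-MT2 (12.7) and 55 the reverse (22.7). Shared controls move both effects in the same direction, and at 3 libraries they were too few to split. The simulated groups hold no true change, so a simulated r reflects only noise and shared libraries. It is not on the scale of an r over genes that changed, here or below. The covariances are nearer to values that can be compared, with a limit. Each gene was simulated at its mean over all libraries, so genes with hardly any counts in a real group vary less than in the data. The simulated covariances may therefore be too small in size, and a gap to them is a description, not a test. The r over the same genes was -0.0843, -0.0931 and -0.0571 without Empty/Empty library A, B and C. It was -0.0814, -0.0757 and -0.0531 where the low-count filter ran again and kept 11733, 11739 and 11732 genes. The covariance in these refiltered fits was -0.0428, -0.04 and -0.027. The effects of Asxl1-MT2 in the 2 backgrounds share no library. They had an r of 0.182 (simulated 0.00086) and a covariance of 0.0525 (simulated 3.3e-05), with 106 genes higher in both (36.3 for independent lists), 38 lower in both (13.3), 7 higher without T618I and lower with it (26.5) and 12 the reverse (18.3). With 1 library left out, over the same genes, this r ran from 0.117 (without Asxl1-MT2/Empty A) to 0.199 (without Asxl1-MT2/Empty C). The effects of T618I in the 2 backgrounds had an r of 0.822 (simulated 0.00045) and a covariance of 1.17 (simulated 1.3e-05), with 1476 genes higher in both (549), 1135 lower in both (420), 30 higher without Asxl1-MT2 and lower with it (465) and 116 the reverse (496). T618I alone and Asxl1-MT2 beside T618I, which share the Empty/T618I libraries with opposite sign, had an r of -0.0905 (simulated -0.49) and a covariance of -0.0692 (simulated -0.019), with 684 genes higher in both (517), 139 lower in both (341), 595 higher with T618I and lower with Asxl1-MT2 (377) and 751 the reverse (467).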

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

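The counts over other splits of the libraries, and the tests of the scaling factors and of the spread between libraries, were chosen before their results were seen, while the tests of the Hoxb8, Csf3r and Asxl1 levels, of the Mcpt family, of a share of mast cells and of the dispersion over other groupings were chosen after. The effect of Asxl1-MT2 differed between the backgrounds with and without T618I, by the edgeR quasi-likelihood test of the interaction, for 2273 genes. Of 100 groupings of the 12 libraries drawn at random, the real one included, 2 gave as many calls, the real one with 2273 and another with 2547, and 95 gave 0. Of the other 99, 0 kept the T618I libraries in groups of their own, and their common dispersion was at least 0.044 against 0.00848 for the real one. Their counts are therefore no test of the interaction. The grouping with 2547 calls had kept the 3 Asxl1-MT2/T618I libraries together and divided those of each other group. Whether this gave its calls was not tested. DESeq2 called 2405 genes for the real grouping.

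Of these genes, 19 were called in opposite directions for Asxl1-MT2 in the 2 backgrounds. They included Ltf, with an interaction log2 fold change of 4.718, Hoxa9, with 5.004, Mfsd6, Col18a1, Asb13, Gmpr, Gng2, Fyb, Them6, Acvr1b, Slc25a23, Vim, Plcb4, Sec24d, Camk2d, Pde4b and Slc2a3. The calls of Ltf and Hoxa9 in the background without T618I were lost when any of 4 and 7 libraries was left out. Lists whose interaction passed both the camera and the fry test had median log2 fold changes of 2.15 (mature neutrophil), 2.09 (secondary granule), 1.25 (NADPH oxidase and phagocyte), 1.16 (monocyte), 0.81 (NF-kB), 0.739 (interferon), 0.656 (immediate early), -0.464 (heat shock) and -0.495 (ribosome biogenesis). With an estimated correlation the camera adjusted p-values of these lists were 0.143, 0.143, 0.143, 0.143, 0.331, 0.222, 0.331, 0.143 and 0.181.

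The rise of mature neutrophil and secondary granule genes in Asxl1-MT2/T618I over Empty/T618I was weighed first. The scaling factors argue little for it, since 54 of 56 genes stayed higher with library size only, and their median log2 fold change went from 2.35 to 2.21. A lower level of the conditional Hoxb8 needs its counts to fall, but Hoxb8 was higher by 0.973 on the log2 scale and Esr1 went from 84.5 ± 16.6 to 160.1 ± 12.8 CPM, which argues against it as far as these counts measure the construct, itself a hypothesis. This holds for that comparison only. Both counts were lower in Empty/T618I than in Empty/Empty, so for T618I alone a lower level of Hoxb8 cannot be told apart from other causes. A higher level of the CSF3R construct cannot be told apart, because Csf3r was higher by 1.63 and the table does not separate the construct from the cells' own gene. Of the JAK-STAT genes 12 rose and 5 fell. The list was higher by the directional fry test (fry adjusted p = 0.00153) but did not pass camera (camera adjusted p = 0.246). This does not decide between a higher level of the receptor and an effect of the truncated Asxl1 itself, and both stay open.

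For the mast cell, basophil and eosinophil genes that rose in Empty/T618I, reads shared within the Mcpt family are argued against by 10 of 15 genes outside that family that rose as well. A share of mast cells or basophils in the cultures cannot be told apart from a change within the cells. Of 9 markers under 20 CPM in Empty/Empty, 7 were higher, where the rule for such a share asked for all of them. The list also holds eosinophil genes, which mast cells or basophils need not raise. The rule was thus too strict, and the markers that were not higher do not count against such a share. The bound of this test was reworded after its value was seen, and markers near the floor keep it open.

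Fewer genes were called for Asxl1-MT2 without T618I (215) than with it (5082). Less of the construct without T618I is argued against by the log2 fold change of Asxl1 in Asxl1-MT2/T618I over Asxl1-MT2/Empty, -0.796. A larger spread is argued against by the median absolute log2 fold change, which was 2.95 times as large with T618I (0.283 against 0.0958). The median SEs of 0.118 and 0.117 rest on a spread estimated over all groups together, so they cannot show a difference in spread. Median SDs of log2 CPM were 0.135 in Empty/Empty and 0.128 in Asxl1-MT2/Empty, against 0.129 in Empty/T618I and 0.121 in Asxl1-MT2/T618I. By the interaction test the Asxl1-MT2 effect differed between the backgrounds for 2273 genes, as given above. What made it differ was not tested, and a dependence on T618I itself stays a hypothesis.

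With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. By adjusted p the real split was the 1 with the most edgeR calls in each comparison, and edgeR called 0 genes in every other split. Every other split mixed libraries of the groups compared, which puts a difference between the groups into the spread within them. Low counts in the other splits are therefore no test of the real one. The real splits gave 3878 calls for T618I alone, 215 for Asxl1-MT2 alone, 5082 for Asxl1-MT2 with T618I, 5761 for T618I with Asxl1-MT2 and 5860 for both against neither. At an unadjusted p under 0.05 they gave 4890, 1263, 5930, 6469 and 6526 genes, and the highest of the other splits 1115, 1584, 751, 533 and 592. For Asxl1-MT2 alone another split was thus higher by that measure. DESeq2 called 3799, 300, 4950, 5537 and 5679 genes in the real splits and at most 31, 52, 3, 0 and 0 in the others.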

How the results depend on the processing

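The settings with library size only, with a filter at 5 CPM and without the letter C libraries were chosen after the results were seen. With an absolute log2 fold change of at least 1 required as well, 1345 genes were called for T618I alone, 81 for Asxl1-MT2 alone, 1156 for Asxl1-MT2 with T618I, 1729 for T618I with Asxl1-MT2, 1724 for both against neither and 716 for the interaction. For Asxl1-MT2 alone 359 genes were called with no low-count filter and 386 without the letter C libraries. With Empty/Empty library A, B or C counted as Empty/T618I, edgeR called 0, 0 and 995 genes for T618I alone (2646, 2506 and 3593 at an unadjusted p under 0.05; 973, 726 and 1874 by DESeq2), 5, 4 and 6 for Asxl1-MT2 alone (39, 33 and 46 by DESeq2), and 711, 636 and 1488 for the interaction (1125, 1011 and 1946 by DESeq2). These labels turned the sign of Gstm1 for Asxl1-MT2 with T618I to -0.04607 (library A) and of the Clec12a interaction to -0.09581, -0.1213 and -0.264. They put libraries unlike Empty/T618I into that group, which raises the spread used for all comparisons. The lower counts under them are therefore no test of the calls.

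With an estimated correlation, the mature neutrophil list no longer passed for T618I alone (median 1.36, camera adjusted p = 0.335), for Asxl1-MT2 with T618I (2.38, 0.138) or for the interaction (2.15, 0.143), nor did the secondary granule list for the last 2 (2.32, 0.138, and 2.09, 0.143). The secondary granule list passed for T618I alone (0.454) by fry, with adjusted p = 0.0277 for 1 direction and 3.45e-07 for any.

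With 1 library left out at a time, the low-count filter ran again and kept 11694 to 11739 genes in place of 11578, so these fits differ in their genes as well. Calls ran from 3189 to 4062 for T618I alone, 4029 to 5408 for Asxl1-MT2 with T618I, 4752 to 5963 for T618I with Asxl1-MT2, 4919 to 6073 for both against neither and 1646 to 2640 for the interaction. For Asxl1-MT2 alone they ran from 60 to 276, with 60 and 106 without Asxl1-MT2/Empty libraries A and B and 101, 104 and 136 without Empty/Empty libraries A, B and C. The mature neutrophil median ran from 1.32 to 1.5 for T618I alone, 2.13 to 2.55 for Asxl1-MT2 with T618I and 1.99 to 2.25 for the interaction, and the secondary granule median from 0.25 to 0.532 (0.454 with all libraries), 2.15 to 2.32 and 1.91 to 2.26. The value of 0.25 came from the filter, which let Lyz2 into the list. Over the same 11578 genes, a setting chosen after the results were seen, the secondary granule medians ran from 0.289 to 0.514, 2.2 to 2.41 and 1.91 to 2.56, and calls for Asxl1-MT2 alone from 60 to 273. Without 1 of the Empty/Empty libraries, the correlation of effects ran from -0.0814 to -0.0531 for T618I alone and Asxl1-MT2 alone (-0.16 with all libraries, and -0.0931 to -0.0571 over the same genes), 0.187 to 0.215 for Asxl1-MT2 in the 2 backgrounds, -0.111 to -0.095 for T618I alone and Asxl1-MT2 with T618I, and 0.802 to 0.812 for T618I in the 2 backgrounds. Other libraries moved the r of Asxl1-MT2 in the 2 backgrounds further. Over the same genes it was 0.117 without Asxl1-MT2/Empty library A and 0.199 without Asxl1-MT2/Empty library C, against 0.182 with all libraries.

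A block for the column letter gave 4285, 317, 5444, 6114, 6168 and 2851 calls in the order of the first paragraph, all within 1.5 times. Whether the letters pair the libraries is not given. The lowest same-letter correlation between groups ran from -0.0606 to 0.0448. Each library matched its own letter best in 3 of 3 cases for Empty/T618I with Empty/Empty and with Asxl1-MT2/Empty, and in 2, 2, 0 and 0 of 3 elsewhere. Among Empty/Empty, Empty/T618I and Asxl1-MT2/Empty the same-letter values were 0.181 to 0.22 for letter C and 0.147 to 0.168 for letter A. For letter B they were -0.0226 to 0.0448. Between Asxl1-MT2/T618I and the other groups, same-letter values ran from -0.0606 to 0.106. The planned filter of 1 CPM in 3 libraries kept the same 11578 genes and so says nothing. Over all settings together, those named above included, 22328 single-gene results were the same, 360 stronger, 1225 weaker and 4 reversed, and 2938 list results were the same, 120 stronger, 116 weaker and 0 reversed. The same also covers results called in neither fit, the filter that kept the same genes, and fits without a library outside the comparison. Many of these results could hardly have changed, so the tally is no measure of how firmly results hold.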

Other observations

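The test of Esr1 against Hoxb8 below was chosen after the group means had been seen. In cells with Asxl1-MT2, T618I also raised genes outside the lists given above for that comparison. Of 20 NF-kB targets, cytokines and chemokines 18 rose and 0 fell (19 and 0 when adjusted over the list alone; camera adjusted p = 3.28e-10, and adjusted p = 0.102 with an estimated correlation). Of 24 NADPH oxidase and phagocyte genes 23 rose and 0 fell (24 and 0 when adjusted over the list alone; camera adjusted p = 1e-15, and adjusted p = 0.102 with an estimated correlation), and of 21 monocyte genes 17 rose and 0 fell, the same numbers when adjusted over the list alone (camera adjusted p = 1.43e-07, and adjusted p = 0.102 with an estimated correlation). Proliferation genes were split at 10 higher and 8 lower with TMM factors, and 2 and 13 or 4 and 12 with upper-quartile factors or library size only. Of 25 ribosome biogenesis genes 0 rose and 15 fell (0 and 18 when adjusted over the list alone; camera adjusted p = 0.000122, and adjusted p = 0.424 with an estimated correlation).

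For the interaction, 1 of 21 progenitor genes was positive and 5 negative, and 2 of 25 ATF4 and unfolded protein response genes were positive and 9 negative (1 and 5, and 2 and 10, when adjusted over the list alone; camera adjusted p = 0.0103 and 0.0128, and adjusted p = 0.393 and 0.331 with an estimated correlation). Of 2273 interaction calls, 2167 were not called for Asxl1-MT2 alone. That comparison called only 215 of all 11578 tested genes (1.86%), so most genes lie outside its calls whatever their interaction. Of 163 genes called for Asxl1-MT2 in both backgrounds 144 went in the same direction. Higher with T618I alone, higher again with Asxl1-MT2 beside T618I and with a positive interaction were 412 genes.

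Esr1, which encodes the estrogen receptor, followed Hoxb8 across the libraries. Its level was 198.5 ± 4.6 CPM in Empty/Empty, 84.5 ± 16.6 in Empty/T618I, 209.7 ± 8.58 in Asxl1-MT2/Empty and 160.1 ± 12.8 in Asxl1-MT2/T618I. Among 11577 tested genes Esr1 ranked 1 by how little its ratio to Hoxb8 varied, with an SD of the log2 ratio of 0.0934 against a median of 0.606 over all genes, and the ratio of Hoxb8 to Esr1 ran from 3.1 to 3.79. As a hypothesis, both counts may come from one conditional transcript that joins Hoxb8 to the estrogen receptor. On that reading the lower Hoxb8 counts with T618I alone would measure the construct and not the gene of the cells, and the table has no reads across such a junction to test it further.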
